A study of Mus musculus with 4 samples.

How the data were processed

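The deposited processed files of a mouse study of dental follicle (DF) and dental papilla (P) at E17 and PN2, stages taken as the labels write them, were analysed. Per the labels, the 4 samples are 2-colour Agilent arrays comparing DF with P at E17, DF with P at PN2, DF PN2 with DF E17, and P PN2 with P E17. Per the file headers, the table of each array holds a pair of linear signal intensity columns named by tissue and stage, for 30146 probes. The deposited values are signal intensity without a log, and whether background was subtracted is not given in the sources used here. Per the submitters' processing notes, images were read with Agilent Feature Extraction 8.5.1.1. A separate deposited value table holds log10 ratios in the order of the sample titles, equal to the log10 ratio of the signals plus a constant per array within 0.001 for 99.997% of probes or more, leaving out 1 probe at the lowest value, -2, in each of the 2 tissue comparisons. As log2 that constant was 0.46 for DF E17 over P E17, -0.09 for DF PN2 over P PN2, 0.32 for DF PN2 over DF E17 and 0.87 for P PN2 over P E17. How the authors derived it is not given in the sources used here.

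Checks of the files showed that a tissue and stage has the same signals in every file where it recurs (100% of 30146 probes identical), which for DF E17 and P PN2 is under different dye labels. The data were therefore taken as 4 signal columns, each from 1 hybridisation. In the file titled P PN2 over P E17 the column that should hold P E17 is headed DF E17 and is identical to DF E17 in 100% of probes, so P E17 was taken from the other file that holds it. The deposited ratios of that array correlate with the signals of P PN2 over P E17 with r of 1.00 and with those of P PN2 over DF E17 with r of 0.449. Because the ratios close the loop of 4 arrays by construction (99.99% of probes within 1e-06), the error and the second route that had been planned from the loop were void and were not used. The spread between probes of the same gene was used as the technical error, a choice made after the files were seen. It may hold more than technical error, since it was wider between P E17 and DF PN2 (SD 0.64) than between DF E17 and DF PN2 (0.47). It covers probes on the same hybridisation and no variation between animals, and the number of arrays, 1 per tissue and stage, limits the precision. One tissue entry reads DF PN3 where the title reads DF PN2, and descriptions of a whole embryo and of stem cell culture stand beside the tissue names; the sample titles were followed.

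Probes were matched to genes by the symbol in the platform table: 25962 probes had 1 symbol, 4184 had none and were left out, and 25858 were matched by gene number to the RefSeq annotation, with 0 symbols updated. They stand for 16039 genes, of which 6749 have several probes and 9290 have 1. No coordinates are given. Signals were turned to log2 with no pseudocount, quantile normalised over the 4 columns and averaged over the probes of a gene. Genes whose highest normalised signal reached 100 were kept (14238). Ratios are differences of log2 signals; the change between stages is the log2 ratio of DF over P at PN2 minus that at E17. A gene was counted as higher or lower past 2-fold, the threshold in the labels, and no p-value was computed.

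The lowest signals of the columns lay between 13.3 and 15.9, and the 5th percentile was 37.5 in DF E17, 66.4 in P E17, 25.7 in DF PN2 and 32.4 in P PN2.

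Before the data were examined, 29 gene lists were fixed, for follicle fibroblasts, papilla regulators, odontoblasts, bone, ameloblasts, epithelium, osteoclasts, leukocytes, neutrophils, erythroid cells, endothelium, pericytes, skeletal muscle, Schwann cells, cartilage, cell cycle, collagens, proteases, the Wnt, BMP and TGF-beta, FGF, Hedgehog and Notch pathways, tooth eruption signals, imprinted genes, interferon-stimulated genes, pluripotency, sex-linked genes and housekeeping genes. Each list's median was compared with 10000 random lists of the same size matched on mean signal in 20 bins. The genes named are, for each comparison, the 10 highest and 10 lowest past 2-fold (6 and 6 for the change between stages), leaving out clone and predicted names, and from each list the 3 highest and 3 lowest members, with all housekeeping and sex-linked genes. The rule was to require the second route as well, which is identical here. Signals under the 5th percentile of all normalised signals, 37.9, were also raised to that percentile for the ratios of named genes and the list medians, a choice made after the files were seen. Another 4 lists were added for tests after the files were seen: granulocyte precursors, B cell precursors, megakaryocytes and X genes escaping inactivation.

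The pipeline was tested on simulated data with 200 changed genes per comparison and noise set from the between-probe spread. That noise was the same at all signal levels and in all columns, unlike in the data. The first-named column was also rescaled and given a constant background. Genes simulated at 3-fold passed 2-fold in the right direction in 95.7% for DF E17 over P E17, 76.0% for DF PN2 over P PN2, 96.0% for DF PN2 over DF E17 and 90.0% for P PN2 over P E17, and genes at 6-fold in 98.0% or more.

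Alternatives chosen beforehand were no normalisation, pairwise loess (span 0.3), the deposited ratio table, no signal filter, the brightest probe of a gene, thresholds of 1.5-fold and 3-fold, and the mean of a list in place of its median. Added after the files were seen were median centring, limma's normexp background correction with offset 50, genes in the upper part of the signal range, the requirement that every probe pass 2-fold, and normalisation targets taken from 3 columns. Intervals are 95% bootstrap intervals over genes (2000 draws). The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.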

Results

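Gene expression was measured in mouse dental follicle and dental papilla at the stages labelled E17 and PN2. The dental follicle (DF) is the connective tissue sac around the developing tooth, and the dental papilla (P) is the mesenchyme inside it that gives rise to dentin-forming odontoblasts and the pulp. The labels describe 4 arrays, which compare the 2 tissues at each stage and the 2 stages in each tissue. The deposited signals hold 1 signal column per tissue and stage, repeated without any difference wherever that tissue and stage recurs. Each of the 4 columns was therefore taken as 1 hybridisation, without a replicate. No p-value was therefore computed. A gene is called higher or lower where its log2 ratio passed 1 in size, which is the 2-fold limit that the labels name, and all values are ratios of the first-named tissue or stage over the second. Of 16039 named genes on the array, 14238 reached a normalised signal of 100 in at least 1 column and were compared. The median signal before normalisation was 290.3 in DF E17, 352 in P E17, 245 in DF PN2 and 205 in P PN2.

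At E17, follicle and papilla were set apart by genes of bone-resorbing cells, leukocytes and collagenous matrix on the follicle side and by odontogenic transcription factors and signals on the papilla side. Igfbp5, a secreted binding protein for insulin-like growth factors, had the highest ratio, with a log2 ratio of 7.65. It was followed by bone sialoprotein (Ibsp, 6.20), the ion exchanger gene Slc9b2 (6.15), ceruloplasmin (Cp, 5.83), C1ql3 (5.74) and the collagenase gene Mmp13 (5.69). Lrrn3 (5.50), matrix Gla protein (Mgp, 5.49), Dhh (5.33) and the extracellular sulfatase gene Sulf1 (5.28) completed the 10 highest. On the papilla side, Xist stood at -7.61, Sall3 at -5.21, C1ql1 at -4.98, Dlx6os1 at -4.98 and Sorcs3 at -4.80. Nebl (-4.78), Plppr1 (-4.72), Tsix (-4.52), Fndc3c1 (-4.51) and the homeobox gene Msx2 (-4.51) followed. The lower signal was under 37.9, the 5th percentile of normalised signals, for 6 of these 20 genes, so their ratios and ranks are less exact. Set against that percentile the log2 ratios were 5.12 for Slc9b2, 5.34 for Lrrn3, 4.44 for Mgp, -6.66 for Xist, -4.16 for C1ql1 and -4.80 for Sorcs3. In all, 1495 genes were higher and 1445 lower in DF E17 than in P E17.

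Of the gene groups fixed beforehand, the osteoclast list stood farthest to the follicle side at E17: 10 of 10 measured genes were higher by the mean of their probes, with a median log2 ratio of 3.07, led by tartrate-resistant acid phosphatase (Acp5, 5.15), cathepsin K (Ctsk, 4.71) and Mmp9 (4.24). Every probe lay on the follicle side in 9 of them, while the probes of Itgb3 stood at 5.48 and -0.87. Of these 9, only Calcr, Mmp9 and Tnfrsf11a have several probes, and a gene with 1 probe cannot fail this check. The macrophage and leukocyte list followed with 12 of 14 higher and a median of 2.46 (Tyrobp 3.73, Cd68 3.62). Of 29 collagen, elastic fibre and proteoglycan genes, 17 were higher and 2 lower (median 1.29), with elastin (Eln) at 5.17, Ogn at 3.94 and Thbs2 at 3.89, against versican (Vcan) at -2.02. Matrix proteases and inhibitors had 9 of 18 higher (median 1.04), and imprinted and fetal growth genes 10 of 13 higher and 0 lower (median 1.4995; H19 3.93, Cdkn1c 3.73). Schwann cell and nerve genes had 6 of 11 higher (median 1.38), led by myelin basic protein (Mbp, 4.36) and Sox10 (3.83), although the 3 probes of Mbp differed with an SD of 2.43. Follicle fibroblast markers were split, with 7 of 15 higher and 2 lower (Lox 3.37, Bmp3 3.11, Foxf2 -1.82), and their median of 0.52 became -0.15 among genes in the upper part of the signal range. In the tooth eruption list, 4 of 9 genes were higher and 2 lower. Higher were the parathyroid hormone receptor gene Pth1r (1.73) and the genes of the osteoclast-forming ligands Tnfsf11 (1.93) and Csf1 (1.53), and lower were Il1a (-1.19) and the chemokine gene Ccl2 (-1.06).

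On the papilla side at E17, 11 of 18 papilla and odontogenic regulators were lower in the follicle and 3 higher (median -2.30). Msx2 (-4.51), Pax9 (-4.29) and Fgf3 (-4.24) were farthest to the papilla side, and Tnc (1.79) and Prrx1 (1.38) lay on the follicle side. Wnt genes had 10 of 22 lower and 2 higher (median -0.75), with Dkk1 at -3.42, Wnt5a at -2.75 and Wnt10a at -2.24 but the inhibitor Sfrp4 at 4.21. The BMP and TGF-beta list went both ways, with 9 of 24 higher and 6 lower and a median of 0.06 (-0.15 without normalisation): Bmp4 (-3.79) and Bmp2 (-3.00) were lower, and Bmp5 (4.24) and Bmp3 (3.11) higher in the follicle. The FGF list likewise held Fgf18 at 4.51 and Fgfr2 at 3.17 beside Fgf3 at -4.24, with 3 of 18 higher and 6 lower. Ameloblast and enamel genes had 4 of 9 lower and 0 higher (median -0.96; Sp6 -2.77), whereas dental and oral epithelium genes had 8 of 18 higher and 0 lower (median 0.68; Cldn1 3.72, Perp 2.03). Hedgehog genes had 2 of 10 higher and 1 lower (Gas1 4.46, Ptch1 -1.71), and Notch genes 4 of 13 higher and 2 lower (median 0.84; Jag1 1.86).

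The spread between probes of the same gene served as a technical error, and at E17 it was 0.58 (SD of the log2 ratio, 6749 genes with several probes). With signals under the 5th percentile raised to it, the osteoclast median was 2.80, Cldn1 3.70 and Wnt10a -1.98, and 8 BMP and TGF-beta genes were higher and 1 Notch gene lower. Of the 17 higher collagen and proteoglycan genes, 16 had every probe on the follicle side, which genes with 1 probe could not fail. Ratios of unchanged genes passed 2-fold in 693 of 13849 genes in the simulation, whose noise was set from that error and whose first-named column had an added background. Without normalisation the split of 50.9% higher moved to 25.5%, and in the deposited ratio table to 60.9%, where the median log2 ratio of all genes was -0.32 and 0.13, respectively, against -0.07 after quantile normalisation.

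At PN2, the follicle was set apart from the papilla by the same osteoclast and leukocyte groups and by granulocyte and red cell genes. The highest ratio was that of Retnlg (7.34), followed by S100a9 (7.16), Cstdc4 (6.98), Csta2 (6.76) and Ngp (6.18), which are genes of neutrophils and of the stefin family of protease inhibitors. Igfbp5 (6.13), Acp5 (6.13), Tmprss5 (6.12), Stfa1 (6.12) and Cstdc5 (5.96) completed the 10 highest. On the papilla side were Sorcs3 (-5.59), Nebl (-5.55), Sall3 (-5.42), Sntg2 (-5.39) and the cell adhesion gene Cntn6 (-5.07), then Plppr1 (-5.03), Dpf3 (-4.79), secretin (Sct, -4.79), the potassium channel gene Kcnt2 (-4.54) and Bmp2 (-4.51). The lower signal was under the 5th percentile for 3 of these 20 genes, whose log2 ratios against that percentile were 5.17 for Tmprss5, -5.22 for Sorcs3 and -5.32 for Sntg2. In all, 1829 genes were higher and 1908 lower in DF PN2 than in P PN2.

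Neutrophil granule genes had 5 of 6 members higher in the PN2 follicle than in the papilla (median 5.56; Ltf 5.59, Lcn2 5.52), against 0 of 6 past 2-fold at E17, where the median was 0.07, the mean -0.10, the median without normalisation -0.54 and that with signals raised to the 5th percentile -0.04. Erythroid genes had 5 of 6 higher (median 2.52; the red cell anion exchanger Slc4a1 4.15, Klf1 2.75), against 1 of 6 at E17, where the median was -0.30, but 0.09 from the deposited ratios. By the mean of their probes all 10 osteoclast genes were again higher (median 3.39, Ctsk 5.81, Mmp9 5.46). Every probe lay on the follicle side in 9, of which only Calcr, Mmp9 and Tnfrsf11a have several, and the probes of Itgb3 stood at 5.34 and -1.29. Also higher were 11 of 14 macrophage and leukocyte genes (median 2.69; Cd53 3.84). Schwann cell and nerve genes had 7 of 11 higher and 1 lower (median 1.77; Sox10 4.69, Tubb3 -2.11), endothelial genes 7 of 15 higher and 0 lower (median 0.91; Sox18 1.93), and pericyte and smooth muscle genes 5 of 12 higher and 2 lower (median 0.88; Pdgfrb 2.38, Kcnj8 -2.17). Follicle fibroblast markers had 8 of 15 higher and 1 lower (median 1.01), with Bmp3 at 5.37 and Fbn2 at -3.30.

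Odontoblast and dentin genes at PN2 had 8 of 14 lower and 2 higher in the follicle (median -1.57), with Dlx3 at -3.53, Wnt10a at -3.05 and Smpd3 at -2.24, against Sparc at 1.95 and Col1a2 at 1.01. At E17, 4 of them were higher and 4 lower, with a median of -0.28 (0.06 from the deposited ratios). Bone matrix genes had 3 of 10 higher and 2 lower, with a median of -0.59 but a mean of 0.13, with Ibsp at 5.02 and Slc13a5 at 2.19, and with Omd lowest at -2.89, while at E17 they had 4 higher and 0 lower (median 0.91). Ameloblast genes had 6 of 9 lower and 1 higher (median -1.17, Sp6 -4.09, Ambn -3.48, but Slc24a4 1.72). Cartilage genes had 5 of 9 lower and 2 higher (median -1.03, Acan -2.70, Sox9 -2.36). Papilla regulators had 9 of 18 lower and 3 higher (median -0.88; Fgf3 -3.76, Bmp4 -2.74), but among genes in the upper part of the signal range their median was 0.32. Pluripotency genes had 3 of 5 lower (median -1.44; Esrrb -2.12) and stood at -1.42 at E17. Skeletal muscle genes were divided, with 2 of 11 higher and 2 lower (Actn3 1.79, Myod1 -1.49) and a median of 0.08 that median centring turned to -0.21, as were Hedgehog genes, with 3 of 10 higher and 3 lower (Gas1 4.99, Shh -2.19).

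With signals under the 5th percentile raised to it, the medians of the neutrophil and osteoclast lists were 5.21 and 3.20, and the ratios were 4.82 for Lcn2, 5.08 for Bmp3, 4.51 for Gas1, 1.35 for Actn3, -2.75 for Wnt10a, -3.27 for Ambn and -1.77 for Esrrb. Of the 7 higher endothelial genes, 6 had every probe on the follicle side, which genes with 1 probe could not fail. The spread between probes was 0.77 (SD of the log2 ratio) in this comparison, the highest of the 4, and 1712 of 14112 simulated unchanged genes passed 2-fold. Without normalisation the share of higher genes moved from 48.9% to 63.3%, and the median log2 ratio of all genes from -0.07 to 0.21, with 0.12 in the deposited ratio table.

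The follicle-papilla differences of the 2 stages were related across genes, with a Pearson r of 0.661 and a Spearman rho of 0.614 over 14238 genes, which are not independent replicates. The 4 columns enter these 2 comparisons once each. Higher at both stages were 862 genes, where independent lists would share 192, and lower at both were 800, where they would share 194. Opposite calls were made for 25 genes in each direction, among them Xist, which was lower in the follicle at E17 (-7.61) and higher at PN2 (1.81).

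**Figure D1:**
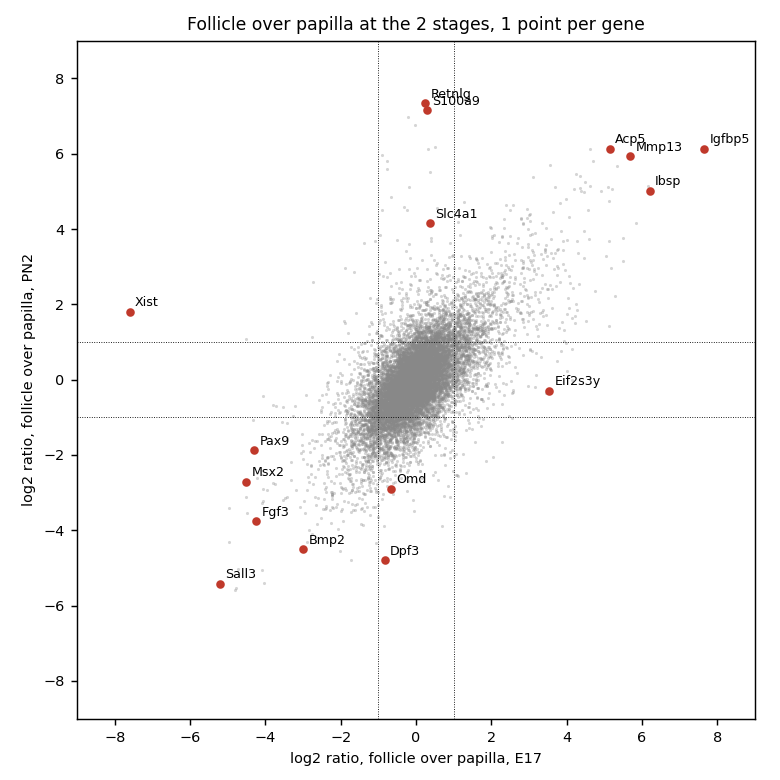
Log2 ratio of follicle over papilla at E17 (horizontal axis) against PN2 (vertical axis), with 1 point per gene for 14238 genes and dotted lines at 2-fold. Most points follow a common diagonal (Pearson r 0.661), Retnlg and S100a9 lie near the vertical axis with ratios over 7 at PN2 alone, and Xist lies apart at -7.61 and 1.81.

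In the follicle, the genes farthest above their E17 level at PN2 were those of granulocytes, together with Xist. The highest ratios of DF PN2 over DF E17 were those of S100a9 (8.26), Cstdc4 (7.58), Retnlg (7.32), Xist (7.20) and lactoferrin (Ltf, 7.05), followed by Stfa1 (6.86), Csta2 (6.77), Cstdc5 (6.63), Ngp (6.62) and Stfa2 (6.43). S100a9 had a normalised signal of 92.8 in DF E17, 75.8 in P E17, 28420 in DF PN2 and 199 in P PN2. The lowest ratios were smaller in size and included 2 Y-linked genes, Ssty1 (-3.04) and Orly (-2.77), with Nlrp5-ps (-2.82), Olfr346 (-2.76), the BMP receptor gene Bmpr1b (-2.74), Klk12 (-2.73), Olfr148 (-2.73), Mrgpra3 (-2.68), Sncg (-2.63) and Fbxw14 (-2.63). For 6 of these 20 genes the lower signal was under the 5th percentile, and against that percentile the log2 ratio was 6.25 for Xist, -2.30 for Nlrp5-ps, -2.04 for Olfr346, -2.41 for Klk12, -1.90 for Olfr148 and -2.39 for Fbxw14. In all, 545 genes were higher and 578 lower in DF PN2, the fewest of the 4 comparisons (7.89% of genes).

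All 6 neutrophil granule genes were higher in DF PN2 than in DF E17 (median 5.68), and so were 5 of 6 erythroid genes (median 1.81), with Slc4a1 at 4.12 and the embryonic globin gene Hbb-y at -1.15. Macrophage and leukocyte genes had 6 of 14 higher and 0 lower (median 0.69; Lyz2 2.39), while 0 of 10 osteoclast genes passed 2-fold (median 0.12, and -0.01 without normalisation). Imprinted and fetal growth genes had 5 of 13 lower and 0 higher (median -0.85; Dlk1 -1.90, Peg10 -1.83, Cdkn1c -1.73). Collagen, elastic fibre and proteoglycan genes had 5 of 29 lower and 0 higher (median -0.29), led by elastin (Eln, -2.25) and decorin (Dcn, -1.07). Wnt genes had 3 of 22 higher, 2 of them by every probe (genes with 1 probe included), and 1 lower (median 0.32, Rspo1 1.56, Dkk2 -1.65). Dental and oral epithelium genes had 4 of 18 higher and 3 lower (median 0.36, Shh 1.87, Krt15 -1.71). Of the papilla regulators only Msx2 (2.33) and Dlx2 (1.03) were higher and Fgf10 (-1.53) lower. In the FGF list Fgf18 (-1.88) and Fgf10 were lower, and in the Notch list Jag2 was higher (1.98, and 1.66 with its signal raised to the 5th percentile) and Jag1 lower (-1.39). No gene passed 2-fold among 15 endothelial genes (median -0.15) and 12 pericyte and smooth muscle genes (median -0.18). The same held for 27 cell cycle genes (median -0.11, but 0.07 in the deposited ratio table), 9 ameloblast genes (median 0.26, but -0.14 without normalisation) and 9 tooth eruption genes (median -0.02, but 0.12 in the deposited ratio table, and a mean of 0.06).

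The spread between probes was 0.47 (SD of the log2 ratio), and 292 of 13692 simulated unchanged genes passed 2-fold. Of the 231 called genes with several probes, every probe was past 2-fold in 111. Without normalisation the share of higher genes moved from 48.5% to 21.2%, and the median log2 ratio of all genes from -0.01 to -0.23.

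In the papilla, 6 of 10 bone matrix genes were higher at PN2 than at E17, and 10 of 27 cell cycle genes and 7 of 18 papilla regulators were lower. The highest ratios of P PN2 over P E17 were those of Csmd1 (4.85), the collagen gene Col24a1 (4.09), Ms4a7 (4.06), the homeobox gene Irx5 (4.05) and the cyclin-dependent kinase inhibitor gene Cdkn1a (3.83). Ccn4 (3.48), Fxyd3 (3.45), the mineralisation phosphatase gene Phospho1 (3.44), Ltbp2 (3.44) and Scin (3.43) followed. Crym was lowest (-5.05), then Cyp1b1 (-4.30), Lmo1 (-3.30), Hdac9 (-3.19), Col8a1 (-3.19), the Wnt receptor gene Fzd1 (-3.11), Tafa3 (-3.10), Zfp109 (-2.90), Olfr30 (-2.64) and Emb (-2.61). For 7 of these 20 genes the lower signal was under the 5th percentile, and against that percentile the log2 ratio was 3.85 for Irx5, 2.55 for Fxyd3, 3.39 for Scin, -4.80 for Crym, -4.07 for Cyp1b1, -2.14 for Zfp109 and -2.12 for Olfr30. In all, 933 genes were higher and 725 lower in P PN2.

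The bone matrix list held no lower gene (median 1.34; Panx3 2.49, osteocalcin, Bglap, 2.42, Ibsp 1.63), and odontoblast and dentin genes had 6 of 14 higher and 0 lower (median 0.92; Col1a1 2.21, Klf4 2.06). The BMP and TGF-beta list had 10 of 24 higher and 1 lower (median 0.85), with Ltbp2 at 3.44, Tgfbi at 1.83, Tgfb1 at 1.79 and Bmp3 at -1.85. Collagen, elastic fibre and proteoglycan genes had 9 of 29 higher and 2 lower (Fmod 2.85, Dcn 2.06), with a median of 0.45 and, without normalisation, -0.20. Epithelium genes had 8 of 18 higher and 2 lower (Shh 3.27, Perp 2.49), with a median of 0.54 and, without normalisation, -0.32. Enamel genes had 3 of 9 higher and 0 lower (Sp6 2.17, Ambn 1.87, Amelx 1.73). Cell cycle and DNA replication genes had 10 of 27 lower and 0 higher (median -0.80; Cdc6 -1.62, Aurka -1.54, Aurkb -1.53). FGF genes had 7 of 18 lower and 2 higher (median -0.62; Dusp6 -2.57, Fgf10 -1.76, Spry2 -1.73, but Fgfr3 1.89), papilla regulators 7 of 18 lower and 1 higher (median -0.75; Lhx8 -2.02, Twist1 -1.89, Pax9 -1.77, but Tnc 1.13), and Wnt genes 6 of 22 lower and 1 higher (Sostdc1 -2.23, Frzb -2.12, but Notum 2.01). Erythroid genes had 3 of 6 lower and 0 higher (median -1.03; Klf1 -1.61). Interferon-stimulated genes had 2 of 8 higher (Oasl2 2.33) and a median of 0.50, which was -0.34 without normalisation. Cartilage genes had 3 of 9 higher (Acan 1.75) and a median of 0.52, which was -0.31 without normalisation and -0.12 without the signal filter. Of the neutrophil granule genes 1 of 6 was higher (S100a9 1.39).

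The spread between probes was 0.65 (SD of the log2 ratio), 1061 of 13952 simulated unchanged genes passed 2-fold, and every probe was past 2-fold in 156 of the 484 called genes with several probes. With signals raised to the 5th percentile, Bmp3 stood at -1.56, Tgfb1 at 1.49 and Spry2 at -1.62, 5 odontoblast and 8 collagen and proteoglycan genes were higher, and 1 epithelium gene was lower. P PN2 had the lowest median signal before normalisation (205), though not the lowest 5th percentile. Without normalisation 127 genes were higher and 4980 lower, and the share of higher genes moved from 56.3% to 2.49%. The median log2 ratio of all genes then moved from -0.02 to -0.80, while the medians of the bone matrix, odontoblast and BMP lists were above 0 at 0.58, 0.20 and 0.08. The epithelium, cartilage, collagen and interferon medians fell below 0 with this shift. They stayed higher than 98.04% or more of the matched random lists.

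The 2 stage comparisons, which also use separate columns, were less alike across genes than the 2 tissue comparisons, with a Pearson r of 0.173 and a Spearman rho of 0.198. Higher at PN2 in both tissues were 91 genes, where independent lists would share 35.7, and lower in both were 78, where they would share 29.4. Opposite calls were about as many as independent lists would give. Higher in the follicle and lower in the papilla were 35 genes (27.8 for independent lists), and 39 went the other way (37.9). Macrophage and leukocyte genes had medians of 0.69 in the follicle and 0.77 in the papilla (-0.08 in the papilla without normalisation), while the erythroid list had 1.81 in the follicle and -1.03 in the papilla.

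**Figure D2:**
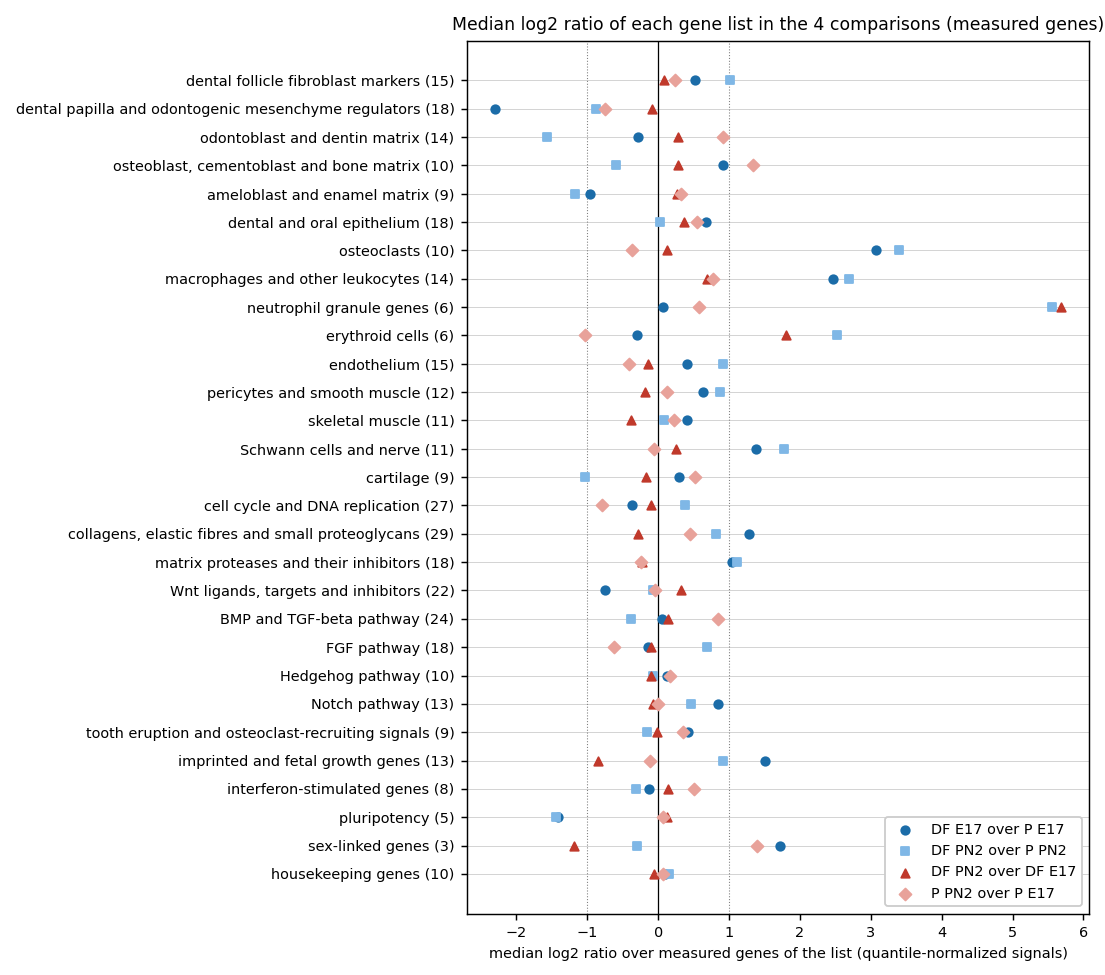
Median log2 ratio (horizontal axis) of each of 29 gene lists in the 4 comparisons, each shown by its own symbol, with the number of measured genes in parentheses and dotted lines at 2-fold. The osteoclast list lies at 3.07 and 3.39 in the tissue comparisons and at 0.12 and -0.37 in the stage comparisons, and the neutrophil list lies over 5 in both comparisons of DF PN2.

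The follicle-papilla difference changed by over 2-fold between the stages in 2458 genes, of which 1156 moved to the follicle side and 1302 to the papilla side at PN2. Xist (9.42, or 8.47 with its DF E17 signal raised to the 5th percentile), Cstdc4 (7.18), Retnlg (7.10), S100a9 (6.86), Cstdc5 (6.86) and Csta2 (6.77) moved farthest to the follicle side. Nrk (-4.16), Wfdc1 (-4.08), Parm1 (-4.03), Rnf180 (-4.01), Dpf3 (-3.96) and Abi3bp (-3.94) moved farthest to the papilla side. Papilla regulators had 10 of 18 members moving to the follicle side and 1 to the papilla side (median 1.05; Pax9 2.42, Dlx2 2.26, Lef1 1.99), and cell cycle genes 11 of 27 and 0 (median 0.96; Aurkb 1.48). Wnt genes had 7 of 22 moving to the follicle side and 2 to the papilla side (median 0.61; Rspo1 3.50, Dkk2 -2.51). Imprinted and fetal growth genes had 7 of 13 moving to the papilla side and 1 to the follicle side (median -1.53, Plagl1 -3.36, Cdkn1c -3.23). In the same order, collagen and proteoglycan genes had 12 of 29 and 1 (median -0.78, Dcn -3.13) and bone matrix genes 6 of 10 and 1 (median -1.12, Panx3 -2.83). Odontoblast genes had 6 of 14 and 0 (median -0.88), and BMP and TGF-beta genes 11 of 24 and 3 (median -0.75, Bmp5 -2.23, Tgfbi -2.17). The spread between probes was 0.77 (SD of the log2 ratio), and P PN2 had the highest estimated between-probe variance of the columns (0.366). No unchanged genes were simulated for this change. In DF PN2 over P PN2, with about that spread, 1712 of 14112 simulated unchanged genes passed 2-fold, so many of the 2458 may reflect probe error. Of 716 called genes with several probes, every probe was past 2-fold in 262. Without normalisation the share moving to the follicle side went from 47.0% to 87.3%, with a median log2 change of 0.52 over all genes.

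Sex-linked genes differed between the 4 columns, so the sex make-up of the tissue may differ between them and was not separated from tissue and stage. Xist, the RNA that silences the inactive X chromosome, had a normalised signal of 19.7 in DF E17, 3846 in P E17, 2890.4 in DF PN2 and 827 in P PN2. The Y-linked gene Eif2s3y had signals of 413, 35.6, 181 and 221 in the same order, and Uty had 580.2, 176, 197 and 461. Their ratios were 3.54 and 1.72 at E17 and -0.29 and -1.22 at PN2 for follicle over papilla, -1.19 and -1.56 for the follicle stages, and 2.64 and 1.39 for the papilla stages. With the P E17 signal of Eif2s3y raised to the 5th percentile, its ratios were 3.44 at E17 and 2.55 for the papilla stages. Of 10 housekeeping genes, 1 passed 2-fold in the E17 tissue comparison (Gusb 1.09), 2 in that at PN2 (Gusb 1.01, Tfrc 1.03) and 0 in either stage comparison. The signs of the smaller housekeeping ratios turned with the scaling, and the list's median in P PN2 over P E17 went from 0.07 (mean -0.02) to -0.73 without normalisation.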

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

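All tests in this part were chosen after the result was seen, except those with the granulocyte precursor list and with the probe spread without normalisation, which were written before their result was seen. Each difference named next was picked because the effect had opposite signs in the 2 tissues or at the 2 stages, with 1 column per tissue and stage, and the difference was not tested.

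Between tissues, the stage effect (PN2 over E17) differed by 2.84 (log2) for the erythroid list, with 1.81 in the follicle and -1.03 in the papilla. It differed by -0.74 for collagens and proteoglycans (-0.29 and 0.45; without normalisation, which shifts all genes, the latter was -0.20 and still above all 10000 matched random lists), by -2.58 for the median of the 3 sex-linked genes (-1.19 and 1.39, with means of 1.48 and 0.60) and by 9.42 for Xist (7.20 and -2.22). Between stages, the tissue effect (follicle over papilla, E17 minus PN2) differed by -0.75 for the cell cycle list (-0.37 and 0.38), by -5.61 for Tsix (-4.52 and 1.09) and by -9.42 for Xist (-7.61 and 1.81). With the DF E17 signal of Xist raised to the 5th percentile of normalised signals, its change between stages was 8.47.

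The first pattern weighed was that Xist was lowest in DF E17 while the Y-linked genes Eif2s3y and Uty moved against it; of the other Y-linked genes named, Ssty1 also had the opposite sign at E17 (0.74), but Orly had that of Xist (-0.23). Over 6 ways of normalising, the smallest ratio of Xist in DF PN2 over DF E17 was 5.77. It was 6.25 with the signal of DF E17 set to the 5th percentile. The size of the ratio thus did not rest on 1 way of normalising. A fall under 2-fold was hardly possible, since leaving out normalisation moved the median of all genes only from -0.01 to -0.23. An exchange of the E17 follicle and papilla labels was argued against by the osteoclast list, whose median of 3.07 (95% interval 2.498 to 4.24) lay on the follicle side, as at PN2. Xist stood against both Eif2s3y and Uty in all 4 comparisons, which are not independent. Tissue from pups of different sex would give such signs, so for these genes sex make-up cannot be told apart from tissue and stage. The test with 4 X-linked genes that escape inactivation did not decide it: their median had the sign of Xist in 3 of the 4 comparisons. It was -0.45 in DF E17 over P E17, 0.35 in DF PN2 over DF E17 and -0.05 in P PN2 over P E17, but -0.18 in DF PN2 over P PN2, where Xist was at 1.81.

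The second pattern was that the measured neutrophil genes, and the measured erythroid genes other than Hbb-y, were highest in DF PN2. The smallest of 6 neutrophil medians in DF PN2 over DF E17 was 4.96 (95% interval 1.98 to 7.09), so its size did not rest on 1 way of normalising. As for Xist, a fall under 2-fold was hardly possible. Blood-forming marrow cells, for example from bone dissected with the follicle, may have been present. The granulocyte precursor, eosinophil and mast cell list had a median of 1.62 (95% interval -0.07 to 2.42, which includes 0), with 6 of 10 higher and 0 lower. Among its genes, Prg3 (0.0044), Epx (-0.31) and Hdc (-0.14) stayed within 2-fold. The mast cell protease gene Mcpt8 stood at 2.62 and Mmp8 at 4.96. These genes were picked after their values were seen. The B cell precursor list had a median of 1.35 (95% interval 0.09 to 1.88) with 6 of 10 higher. Both lists hold genes that mature blood cells may also express, such as Mmp8 in the first and Cd79a in the second. They thus cannot tell marrow precursors from circulating blood without them, which stays open. The megakaryocyte and platelet list had 1.08 with 3 of 6 higher. A change of the follicle with age, which the design also contains, was not tested, and the signal of Hbb-b1 was 4997 in DF E17 and 13318 in DF PN2.

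The third pattern was that probes of the same gene differed more where P PN2 was compared. The estimated variance was 0.366 for P PN2, 0.140 for DF E17, 0.162 for P E17 and 0.186 for DF PN2. That estimate takes the variances of 2 columns to add up and allows for no part that belongs to a difference between tissues. Without P PN2, the SD was 0.64 between P E17 and DF PN2 and 0.47 between DF E17 and DF PN2. Between P E17 and P PN2 it was 0.65. The spread was thus not tied to P PN2 alone and may hold more than technical error. Dim signals as the whole cause were argued against by the brightest genes. In these the SD of DF PN2 over P PN2 was 2.16 times that of DF PN2 over DF E17 (95% interval 2.04 to 2.28). That quotient sets a tissue against a stage comparison, so it also holds any difference between tissues. Like comparisons of the brightest genes differed too, with 0.68 for DF PN2 over P PN2 and 0.39 for DF E17 over P E17. The SD of the stage comparisons was 0.54 in the papilla and 0.31 in the follicle. Without any normalisation that quotient was 1.53 (95% interval 1.49 to 1.56), and it too sets a tissue against a stage comparison. Unnormalised ratios also ran with signal, which can widen the spread between probes. From the dimmest to the brightest probes their median went from -0.43 to 0.46 in DF PN2 over P PN2. In DF PN2 over DF E17 it went from -0.54 to -0.11. How far quantile normalisation added to the spread thus stays open. RNA degradation in P PN2 stays open, since probe positions along the transcripts were not used here. No biological explanation was tested.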

How the results depend on the processing

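Median centring, normexp, the upper part of the signal range (8020 genes), the every-probe rule and the 3-column targets were chosen after the files were seen, as was loess for lists and named genes. Counts below run in the order higher and lower in DF E17 over P E17, in DF PN2 over P PN2, in DF PN2 over DF E17 and in P PN2 over P E17, then the change between stages.

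Pairwise loess, the deposited ratio table, no signal filter, the brightest probe, median centring and the 3-column targets left every count they could give within 1.5 times the value reported. The every-probe rule did so too, but a called gene with 1 probe cannot fail it. Among called genes with several probes, it kept 497 of 955 at E17, 530 of 1134 at PN2, 111 of 231 in the follicle stages, 156 of 484 in the papilla stages and 262 of 716 for the change. A threshold of 1.5-fold gave 2713, 3229, 3291, 3674, 1528, 1556, 2395, 2243 and 5527, and 3-fold gave 698, 427, 826, 764, 191, 178, 235, 136 and 791, by construction. The upper part of the signal range gave 744, 492, 958, 792, 168, 145, 461, 337 and 1054, from fewer genes. No normalisation moved 7 counts: 921 and 2685 at E17, 2804 higher at PN2, 1357 lower in the follicle stages, 127 and 4980 in the papilla stages, and 3781 for the change, following the shift of all genes. Normexp, whose offset shrinks ratios of dim genes, gave 920 lower at E17, 352 and 301 for the follicle stages and 602 and 426 for the papilla stages.

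Of 1285 recomputed list medians, 35 entered the outer range of random lists, 33 left it, and 12 that had lain in it changed sign; another 111, of up to 0.59 in size, changed sign without having been in it. In P PN2 over P E17 without normalisation the medians were -0.32 for epithelium, -0.078 for macrophages, -0.31 for cartilage, -0.20 for collagens and -0.34 for interferon-stimulated genes, and the change for epithelium was 0.068, against medians of -0.80 and 0.52 over all genes. These signs followed the shift of all genes. The medians in P PN2 over P E17 stayed higher than 98.04% or more of matched random lists, and the epithelium change stayed at percentile 1.33. In the upper part of the signal range, follicle fibroblasts had -0.15 at E17 and papilla regulators 0.32 at PN2, and cartilage without the filter had -0.12 in the papilla stages; the cause was not tested. The mean of the sex-linked list, in which Xist outweighs the Y-linked genes, was -0.79 in DF E17 over P E17, 1.48 in DF PN2 over DF E17 and 0.88 for the change. Ratios of named genes were recomputed only for the highest and lowest genes of each comparison and the housekeeping and sex-linked genes (154 ratios). The other named list members were not recomputed. Of the 1192 recomputed values, 35 changed sign, all from ratios of up to 0.52 in size and none from a ratio past 2-fold. Of the 1192, 80 moved by more than the probe spread (39 with normexp, 33 without normalisation).

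The loop least-squares estimate, the indirect path, the mean of both routes, the loop closure SD and plain background subtraction were not run, because the ratios close by construction and no background values were used here. Weak signals limit the dim genes: the between-probe SD of DF E17 over P E17 was 0.74 among the dimmest genes and 0.39 among the brightest.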

Other observations

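Nothing in this part was tested. Matrix proteases lay on the follicle side at PN2 as well, with 10 of 18 higher and 1 lower (median 1.11; Mmp13 5.94, Mmp3 -1.33). Collagens and proteoglycans had 12 of 29 higher and 4 lower there (median 0.82), with Ogn at 2.90 and Fbn2 at -3.30. FGF genes had 5 of 18 higher and 4 lower (median 0.69), and the BMP and TGF-beta list 6 of 24 higher and 10 lower (median -0.38), with Bmp2 at -4.51 and Bmp7 at -2.98.

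The 4 columns ranked genes most alike between the stages of a tissue, with a Spearman rho of 0.949 for DF E17 and DF PN2 and 0.930 for P E17 and P PN2. Between tissues rho was 0.888 at E17 and 0.859 at PN2.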
